A study of Mus musculus with 2 samples.

How the data were processed

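H3K27me3 was measured by chromatin immunoprecipitation and sequencing in hindbrain of mixed-sex B6NCrl embryos at embryonic day 12.5, in 2 biological replicates pooled from 120 and 88 embryos, with a size range of 300 to 500 bp per the labels. The values used were 4 peak lists on mm10: replicate 1, replicate 2, both replicates pooled, and replicated peaks, which per the file headers were derived from the other 3. The peak caller, its version, its control and its threshold are not given in the sources used here. The fold of each peak is the value the authors' caller gave, taken as enrichment over the caller's background, an assumption since the headers do not say what it is relative to. The −log10 p and −log10 q of each peak are also values of the authors' caller, as deposited. The smallest −log10 p was 2.00 in each replicate's list. Reads, signal tracks and control libraries were not analysed here, so the depth is unknown and no interval that needs it was computed.

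Genes were the 21938 protein-coding genes of GENCODE mouse release 21 on GRCm38 patch 6. The transcription start site (TSS) of a gene was the 5′ end of its annotation. A gene was called marked when peaks covered at least 500 bp of the 2 kb window reaching 1 kb to each side of the TSS. The replicated list was used for the main values, and the replicates' own lists for means and SDs over n = 2. A promoter was CpG-rich when the 1 kb around its TSS had an observed over expected CpG of at least 0.6 and a GC content of at least 55%. Domains were replicated peaks merged across gaps of up to 1 kb.

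Of the 51 gene lists, 21 were curated from general knowledge and 30 were families defined by gene symbol. They were compared with all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 51 lists and a threshold of 0.05, for lists with at least 5 members. Hox paralogs 9 to 13 and 1 to 4 were compared by a permutation test with 100000 resamples, CpG classes and X against autosomes by Fisher's exact test, chromosome coverage by the exact rank of X among 20 chromosomes, and replicates' marked genes by an exact McNemar test. Overlap between replicates and the share of covered bases in TSS windows were set against 100 shuffles of peaks within chromosomes. Genes are not independent replicates, so these tests describe genes of these libraries and not a population of embryos.

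Genes were named by rule: from each curated list up to 4 marked members with the highest coverage of the window (mean of the replicates' own lists, ties by mean fold) and up to 2 members not marked with the lowest coverage (ties in alphabetical order), up to 3 marked members of each family, every Hox gene, genes in the 10 widest domains, the 10 marked genes of highest mean fold, and the 5 genes in each direction with the largest difference in coverage between replicates. Prdm16 falls outside the rule and was chosen after its values were seen. Lists, thresholds, tests, the naming rule and most alternatives were fixed before the data were examined. Alternatives were stricter q thresholds of 0.05 and 0.001, other overlap and coverage minimums, each replicate's own list, the pooled list, a window of 2.5 kb on each side, CpG-rich promoters only, 1 gene per 100 kb and other gaps. Principal transcript starts, leaving out chromosome Y, Hox genes by fold, and X with equal numbers of peaks were added after the data had been seen.

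For X, 1 Mb bins with at least 900000 known bases were used, with 5 autosomal bins matched to each X bin by GC and soft-masked share and 2000 bootstrap draws for 95% intervals. The gene list test was tested on simulated data: in 20 simulations over 21938 genes, with 60% of members marked in planted lists and 15% of other genes, 85 of 100 planted lists and 10 of 771 other lists (1.30%) were called. Each gene was drawn independently of its neighbours, so the 1.30% need not hold where genes share a domain. Shared bases and TSS windows showed 0 differences from bedtools. The work used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, pysam 0.24.0, bedtools 2.31.1 and samtools 1.23.1.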

Results

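H3K27me3, the trimethylation of histone H3 that polycomb repressive complexes lay down and that is associated with silent genes, was mapped by chromatin immunoprecipitation and sequencing in hindbrain of B6NCrl mouse embryos at embryonic day 12.5. The 2 libraries formed 1 group of biological replicates, both pooled from embryos of mixed sex: replicate 1 from 120 embryos and replicate 2 from 88. Hindbrain is the part of the neural tube that gives rise to medulla, pons and cerebellum. With 1 group and no second condition, the comparisons were between genes, gene groups, chromosomes and regions, and between the replicates. Replicate 1's own peak list held 129989 peaks over 54.3 Mb, 2.06% of chromosomes 1 to 19 and X, and replicate 2's held 79149 peaks over 33.6 Mb, 1.28%. The authors' replicated list, which combines both, held 56974 peaks over 44.0 Mb, or 1.67%. Read depth is unknown from peak lists, so the replicates' different yields were not set against depth, and a promoter without a peak was not detected as marked rather than shown to lack the mark. Peak folds are the authors' own values, taken here as enrichment over their caller's background.

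The highest peaks at promoters lay at genes of several kinds. By the mean of the replicates, the highest fold within 1 kb of a transcription start site (TSS) was 14.2 ± 0.789 (SD, n = 2) at Adra2c, an adrenergic receptor gene. Next came Wnt3a, a ligand of the Wnt family, with 14.1 ± 1.22 (SD, n = 2), and Neurog3, a proneural factor known for its role in endocrine pancreas, with 13.9 ± 0.767 (SD, n = 2). Helt, Hoxc12, Obscn, Cyp26c1, Six3, Cilp2 and Kcnq1 completed the 10 highest, with means between 12.5 and 12.9. Of 21938 protein-coding genes, 3390 were marked, 15.5%, meaning that replicated peaks covered at least 500 bp of the 2 kb around the TSS. Of these 3390 genes, 2643 were also marked by the own lists of both replicates and 123 by neither. In 844 genes the whole window was covered.

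Replicate 1's own list marked 3488 genes and replicate 2's 2745, giving 14.2% ± 2.39 (SD, n = 2) of genes. Both lists marked 2652 genes, while 836 were marked by replicate 1's list alone and 93 by replicate 2's alone (exact McNemar test, two-sided, p = 3.9e-150, over genes of these 2 libraries). The promoters with the largest excess of coverage in replicate 1 were those of Zc3h12a, an RNase that degrades inflammatory mRNAs, with a difference of 72.1 percentage points, Lrrc3b with 71.5, Nrn1 with 69.3, Slc45a1 with 67.3 and Nexn with 66.3. In the other direction, differences of replicate 1 minus replicate 2 were -45.1 at Ptp4a2, -41.4 at Lrrc36, -40.5 at Kctd19, -39.1 at Adgrg1 and -38.8 at Acot4. Zc3h12a, Lrrc3b, Slc45a1 and Nexn were marked by replicate 1's list and not by replicate 2's.

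Gene groups fixed beforehand were each compared with all other genes, and not with one another, in how many of their promoters were marked. Of 51 lists tested, 32 had a higher share of marked genes than all other genes, 7 had a lower share and 12 did not pass the test (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 51 lists, threshold 0.05). Every member was marked in 7 lists. All adjusted p-values given for lists are from this test, which treats genes as independent although neighbours can share a domain and some genes stand in several lists. When 1 gene per 100 kb was kept, 42 lists still had enough members, with 18 above and 4 below the rest.

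**Figure D1:**
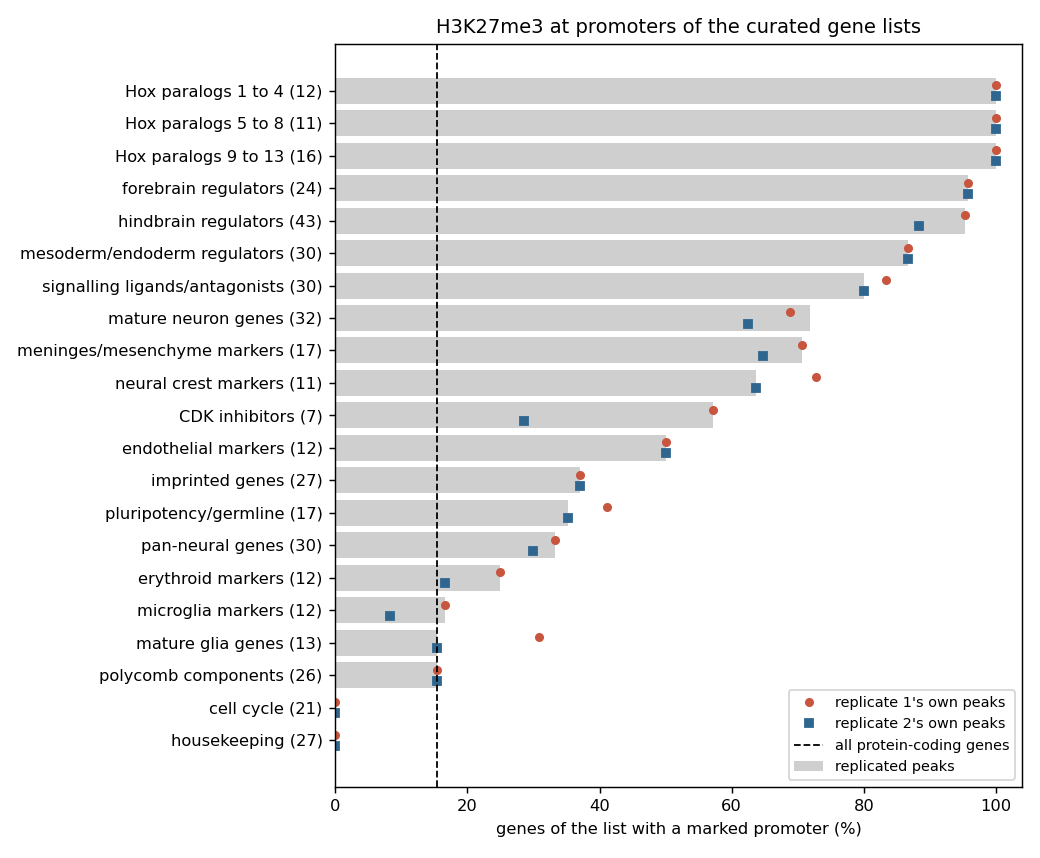
Percent of the genes of each curated list (number of members in parentheses) whose promoter was marked by replicated peaks (bars), by replicate 1's own peaks (circles) and by replicate 2's own peaks (squares), with the 15.5% of all protein-coding genes as a dashed line. Hox genes reached 100%, and no housekeeping or cell cycle gene was marked.

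Most regulators of the hindbrain's own patterning, of the forebrain and of mesoderm and endoderm were marked, and the differences between these lists were not tested. Among regulators known from hindbrain development, 41 of 43 were marked (91.9% ± 4.93 by the replicates' own lists, SD, n = 2, Fisher's exact test, adjusted p = 7.6e-30). Wnt1, a signal of the midbrain-hindbrain boundary, Nkx2-2, a ventral progenitor factor, Phox2a, a factor of noradrenergic and cranial motor neurons, and Fev, a factor of serotonergic neurons, had their whole windows covered in both replicates. Their highest folds were 12.035 ± 0.455, 10.3 ± 0.552, 9.40 ± 0.248 and 8.59 ± 0.888 (SD, n = 2). The 2 members not marked were Meis1 and Meis2, cofactors of Hox proteins, where neither replicate had a peak in the window. Forebrain regulators were marked in 23 of 24 cases (Fisher's exact test, adjusted p = 4.4e-17). Six3, an eye and forebrain factor, had a fold of 12.6 ± 1.69 (SD, n = 2), Fezf2, a factor of cortical projection neurons, 8.99 ± 2.98, Rax, a retinal factor, 6.37 ± 0.665, and Dlx5, a factor of ventral forebrain, 4.79 ± 0.751. Hesx1, a pituitary factor, was the forebrain gene not marked. Of regulators of mesoderm and endoderm, 26 of 30 were marked (Fisher's exact test, adjusted p = 9.3e-17), among them T, the brachyury gene, at 12.2 ± 0.0729 (SD, n = 2), Foxf1 at 11.987 ± 1.57, the muscle factor Myod1 at 10.1 ± 0.824 and Tbx1 at 9.83 ± 1.02. The liver factor Hnf4a and the muscle factor Myog had no peak in the window in either replicate.

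Several families of transcription factors were marked throughout, and others in part. All 9 Pax genes (Fisher's exact test, adjusted p = 1.5e-07), all 8 Lhx genes (8.7e-07), all 14 Nkx genes (1.7e-11) and all 6 Irx genes (3.3e-05) were marked. Replicate 2's own list marked 2 of the 6 Irx genes, and the Irx call was lost with that list (Fisher's exact test, adjusted p = 0.20) and with 1000 bp required (0.19). Irx4 was fully covered in both replicates, while Irx1, marked by replicate 1's list only, was covered over 36.6% ± 24.2 (SD, n = 2) of its window. Of the Fox genes 28 of 44 were marked (Fisher's exact test, adjusted p = 2.7e-12), led by Foxf1, Foxn4 and Foxq1. Marked members numbered 10 of 19 in the Sox family (3.6e-04), 9 of 13 in Tbx (4.5e-05), 5 of 6 in Gata (8.1e-04) and 4 of 6 in the sine oculis family (0.010, Fisher's exact test, adjusted). The call for this last family was lost among CpG-rich promoters alone (3 of 5, adjusted p = 0.068, Fisher's exact test).

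Signalling genes were taken as 1 curated list and as families, and no family was tested against another. Of 30 ligands, antagonists and retinoid-degrading enzymes, 24 were marked (81.7% ± 2.36 by the replicates' own lists, SD, n = 2, Fisher's exact test, adjusted p = 5.3e-14). Cyp26c1 and Cyp26a1, neighbouring genes for enzymes that break down retinoic acid, had folds of 12.7 ± 0.0694 and 10.6 ± 2.92 (SD, n = 2), Wnt10b 9.07 ± 1.18 and the hedgehog ligand Ihh 7.95 ± 1.27. Cyp26b1 and Fgf10 had no peak in the window in either replicate. Of Wnt genes 18 of 19 were marked (Fisher's exact test, adjusted p = 2.5e-13), of Fgf genes 11 of 22 (3.2e-04) and of Bmp genes 7 of 11 (7.1e-04). With 1 gene per 100 kb the Fgf and Bmp calls were lost (Fisher's exact test, adjusted p = 0.12 and 0.060). Eph receptors and ephrins, guidance molecules that also separate hindbrain segments, were marked in 8 of 22 cases (Fisher's exact test, adjusted p = 0.019), a call lost among CpG-rich promoters (0.39) and with 1 gene per 100 kb (0.55). Semaphorins were marked in 6 of 20 cases and did not pass (Fisher's exact test, adjusted p = 0.13), but passed with replicate 1's own list (8 of 20, adjusted p = 0.012), with the pooled list (0.0062) and with 1 bp required (0.0052).

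Genes of mature neurons, potassium channel genes and serotonin receptor genes were marked in most cases. Their shares were compared with all other genes and not with that of pan-neural genes. Of 32 genes of mature neurons, 23 were marked (65.6% ± 4.42 by the replicates' own lists, SD, n = 2, Fisher's exact test, adjusted p = 5.9e-12). Chat and Slc18a3, the nested cholinergic genes, shared a fold of 8.60 ± 0.337 (SD, n = 2), Slc32a1, the vesicular inhibitory amino acid transporter, had 6.92 ± 1.43 and Slc6a3, the dopamine transporter, 6.62 ± 0.550. The GABA receptor genes Gabra6 and Gabrg2 had no peak in either replicate. Potassium channel genes were marked in 60 of 94 cases (Fisher's exact test, adjusted p = 4.3e-25), led by Kcnj12, Kcnk9 and Kcns1, and serotonin receptor genes in 11 of 14 (7.7e-07), led by Htr6. Ionotropic glutamate receptor genes were marked in 7 of 16 cases (Fisher's exact test, adjusted p = 0.010), a call lost with 1 gene per 100 kb (0.16). GABA-A receptor genes were marked in 6 of 19 cases and did not pass (Fisher's exact test, adjusted p = 0.13), though they passed among CpG-rich promoters (5 of 6, 0.0021), with 1000 bp required (0.023) and with windows of 2.5 kb on each side (0.027). Pan-neural genes, which progenitors or most neurons use, were marked in 10 of 30 cases (31.7% ± 2.36 by the replicates' own lists, SD, n = 2, Fisher's exact test, adjusted p = 0.025). The intermediate filament gene Ina was covered over 91.3% ± 1.03 (SD, n = 2) of its window, Sox1 over 84.4% ± 11.5, Elavl3 over 69.2% ± 12.3 and Nefl over 60.9% ± 32.5. Elavl4 and the radial glia gene Fabp7 had no peak in either replicate, and the pan-neural call was lost with 1 gene per 100 kb (Fisher's exact test, adjusted p = 0.33).

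Markers of other cells that dissected hindbrain tissue can hold were tested list by list, and the lists were not tested against one another. Markers of meninges and mesenchyme were marked in 12 of 17 cases (Fisher's exact test, adjusted p = 1.3e-06), with a fold of 12.2 ± 3.91 (SD, n = 2) at Twist2, 6.87 ± 0.0630 at Alx3, 6.79 ± 1.35 at Alx1 and 6.22 ± 0.383 at Alx4. Col3a1 and Dcn, genes of extracellular matrix proteins, had no peak in the window in either replicate. Neural crest markers were marked in 7 of 11 cases (Fisher's exact test, adjusted p = 7.1e-04), including Tfap2a, Sox10, Erbb3 and Foxd3 and not the myelin gene Mpz or the endothelin receptor gene Ednrb. Endothelial markers were marked in 6 of 12 cases (Fisher's exact test, adjusted p = 0.0089, lost with 1 gene per 100 kb at 0.060), with Sox18, Cldn5 and Esam fully covered, Flt1 covered over 98.6% ± 2.05 (SD, n = 2) and Egfl7 and Emcn without a peak. Erythroid markers (3 of 12, Fisher's exact test, adjusted p = 0.47), microglia markers (2 of 12, 1.00) and mature glia genes (2 of 13, 1.00) did not differ from other genes by the test. Lists this short could not pass as lower, since the cell cycle list did not with 0 of 21 marked. Replicate 2's own list marked 1 of the microglia markers, and replicate 1's marked 4 of the mature glia genes. The lists' marked members were Epor, Klf1 and Hba-x, then C1qc and C1qa, then Olig1, a factor of oligodendrocyte precursors, with a fold of 11.4 ± 1.32 (SD, n = 2), and the myelin gene Mbp. Alas2, Gata1, Aif1, Cd68, Aldh1l1 and Aldoc had no peak in either replicate. Of collagen genes 26 of 44 were marked (Fisher's exact test, adjusted p = 1.6e-10), led by Col8a2, Col13a1 and Col15a1. Cadherins with numbered symbols (5 of 23, 0.45), keratins (5 of 49, 0.47) and clustered protocadherins (8 of 57, 1.00) did not pass (Fisher's exact test, adjusted). Protocadherins passed as lower with 1000 bp required (1 of 57, Fisher's exact test, adjusted p = 0.017), and replicate 2's own list marked 3 of them. The epithelial genes Cdh1, Krt8 and Krt18 were among those marked, with windows covered over 100% ± 0, 89.0% ± 3.32 and 87.1% ± 5.34 (SD, n = 2).

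Several cell cycle inhibitors were marked while no gene of the cell cycle machinery was. Cdkn2a and Cdkn2b, the inhibitor genes of the Ink4 locus, lay in one domain and were covered over 100% ± 0 and 95.4% ± 6.47 (SD, n = 2) of their windows. Cdkn1a and Cdkn2c, marked by replicate 1's list only, were covered over 34.1% ± 15.5 and 30.2% ± 8.03 (SD, n = 2), and Cdkn1b and Cdkn2d had no peak. That gave 4 of 7 inhibitor genes (Fisher's exact test, adjusted p = 0.019), a call lost with replicate 2's own list (2 of 7, adjusted p = 0.25), with 1000 bp required (0.22) and among CpG-rich promoters (0.11). Of 21 cell cycle genes, including Aurka and Aurkb, none was marked (Fisher's exact test, adjusted p = 0.080, passing with replicate 1's own list at 0.047, with the pooled list at 0.048 and with 1 bp required at 0.018). No lower share was possible, so a list of this size could not pass as lower in the main setting. No gene of 27 with housekeeping functions was marked, Actb and B2m included (Fisher's exact test, adjusted p = 0.022, odds ratio 0, 95% interval 0 to 0.800). The housekeeping call was lost with replicate 2's own list (0 of 27, Fisher's exact test, adjusted p = 0.057). It was also lost with 1000 bp required (Fisher's exact test, adjusted p = 0.087) and with 1 gene per 100 kb (0 of 11, 0.31). No lower share than 0 is possible, so these losses do not speak against a low share.

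Large gene families used in other tissues, or in every cell, were mostly free of called mark. Of 1135 olfactory receptor genes 1 was marked, Olfr95 (Fisher's exact test, adjusted p = 1.1e-81), and of 331 vomeronasal receptor genes none (1.2e-23). Replicate 1's own list marked 2 olfactory receptor genes and replicate 2's 0. Zinc finger genes with Zfp symbols were marked in 16 of 394 cases (Fisher's exact test, adjusted p = 2.5e-12), led by Zfp853, Zfp296 and Zfp385c. Histone genes were marked in 0 of 67 cases (Fisher's exact test, adjusted p = 5.2e-05) and respiratory complex genes with Nduf symbols in 1 of 46 (0.011), the one being Ndufa4l2. Both calls were lost with 1 gene per 100 kb (Fisher's exact test, adjusted p = 0.71 and 0.77). That setting kept 7 histone genes, 0 of them marked, and 13 Nduf genes, 1 of them marked. With 0 of 7 no lower share was possible, so it could not have called histone genes lower. The Nduf call was also lost with 1000 bp required (Fisher's exact test, adjusted p = 0.079). Of 79 ribosomal protein genes 1 was marked, Rpl3 (Fisher's exact test, adjusted p = 1.2e-04), but only at the gene's annotated 5′ end: at the start of its principal transcript 0 bp were covered. The same held for Psmd5, which with Psmb8 and Psmb9, subunits of the immunoproteasome, was among the 4 of 39 marked proteasome genes (Fisher's exact test, adjusted p = 0.55). Cytochrome P450 genes were marked in 11 of 100 cases (Fisher's exact test, adjusted p = 0.32), and Cyp26c1, Cyp26a1 and Cyp24a1, the vitamin D hydroxylase gene, led them.

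Pluripotency and germline genes, polycomb genes and imprinted genes each held some marked promoters. Pou5f1, the pluripotency factor gene, was covered over 100% ± 0 (SD, n = 2), Utf1 had a fold of 9.17 ± 0.331, and Prdm14 was covered over 84.6% ± 0.318 and Tdgf1 over 78.7% ± 7.50, while the germ cell genes Asz1 and Dazl had no peak. With 6 of 17 genes marked the list passed (Fisher's exact test, adjusted p = 0.047), but not with 1 bp required (0.079), with 1 gene per 100 kb (0.087) or among CpG-rich promoters, where 1 of 6 was marked (1.00). Of 26 polycomb genes 4 were marked (Fisher's exact test, adjusted p = 1.00): Phf19, Pcgf5, Pcgf1 and Cbx4, with Bmi1 and Cbx6 among those without a peak. Imprinted genes were marked in 10 of 27 cases (37.0% ± 0, SD, n = 2, Fisher's exact test, adjusted p = 0.0087), with folds of 12.5 ± 2.01 (SD, n = 2) at Kcnq1, 11.8 ± 2.16 at Slc22a3, 9.03 ± 0.715 at Ascl2 and 8.50 ± 3.35 at Phlda2. Impact and Magel2 had no peak in the window. The imprinted call was lost at principal transcript starts (8 of 27, Fisher's exact test, adjusted p = 0.074, a setting chosen after seeing the data) and among CpG-rich promoters (3 of 11, 0.48).

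All 39 Hox genes, which set the identity of segments along the body axis, were marked in every list. Paralogs 1 to 4, whose known expression reaches into the hindbrain (12 genes, Fisher's exact test, adjusted p = 6.2e-10), paralogs 5 to 8 (11 genes, 3.8e-09) and paralogs 9 to 13, which act further back (16 genes, 5.8e-13), were each marked without exception. Replicated peaks covered 97.1% ± 7.72 (SD over 16 genes) of the window at paralogs 9 to 13 and 95.3% ± 8.64 (SD over 12 genes) at paralogs 1 to 4, a difference of 1.78 percentage points within the spread (permutation test, two-sided, p = 0.55). Replicate 1's own list gave a difference of 4.77 (permutation test, p = 0.26) and replicate 2's of 13.6 (permutation test, p = 0.016). The least covered was Hoxa2, the gene of the second rhombomere's identity, with 49.9% ± 24.4 (SD, n = 2) and a fold of 3.98 ± 0.415. Hoxa1 and Hoxa5 were covered over 69.4% ± 18.4 and 68.7% ± 37.4 (SD, n = 2), and Hoxb9, Hoxc10, Hoxc11 and Hoxd13 over 100% ± 0.

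The height of the peaks was compared between the same Hox groups after the coverage had been seen. The authors' highest fold in the window averaged 9.97 ± 1.76 (SD over 16 genes) at paralogs 9 to 13 and 7.45 ± 2.88 (SD over 12 genes) at paralogs 1 to 4 (permutation test, two-sided, p = 0.010). Replicate 1's own list gave 9.71 against 7.78 (permutation test, p = 0.015) and replicate 2's 8.63 against 6.08 (permutation test, p = 1.2e-04). These tests permuted genes across clusters, on which the groups drew unequally. HoxC held 1 of the 12 and 5 of the 16 genes, and HoxB 4 and 2. Cluster was therefore not separated from the difference. In the HoxB cluster the mean fold of the replicates was 6.10 over Hoxb1 to Hoxb4, 8.49 over Hoxb5 to Hoxb8 and 10.1 over Hoxb9 and Hoxb13. For the same groups of paralogs it was 6.49, 8.24 and 8.32 in HoxA and 8.88, 8.81 and 10.1 in HoxC. In HoxD it was 7.97, 5.96 and 8.50. By annotated starts the middle group thus did not lie between the others in HoxC and HoxD. However, the first group of HoxC and the middle group of HoxD held 1 gene each. In HoxD the order of paralogs 1 to 4 and 9 to 13 depended on the list. Replicated peaks gave 9.41 at paralogs 1 to 4 and 9.08 at paralogs 9 to 13. Replicate 1's own list gave 9.60 and 8.79, and replicate 2's 6.34 and 8.22. These orders were not recomputed at principal transcript starts. Several windows share a peak, as those of Hoxd3 and Hoxd4, whose annotated starts lie at 74711927 and 74711929 on chromosome 2, so the genes are not independent. The annotated start of Hoxc5 (102967443) lies near that of Hoxc10 (102966796), with the same folds. That of Hoxa3 lies between those of Hoxa6 and Hoxa7. At principal transcript starts the folds were 10.1 and 6.91 (permutation test, p = 7.0e-04).

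**Figure D2:**
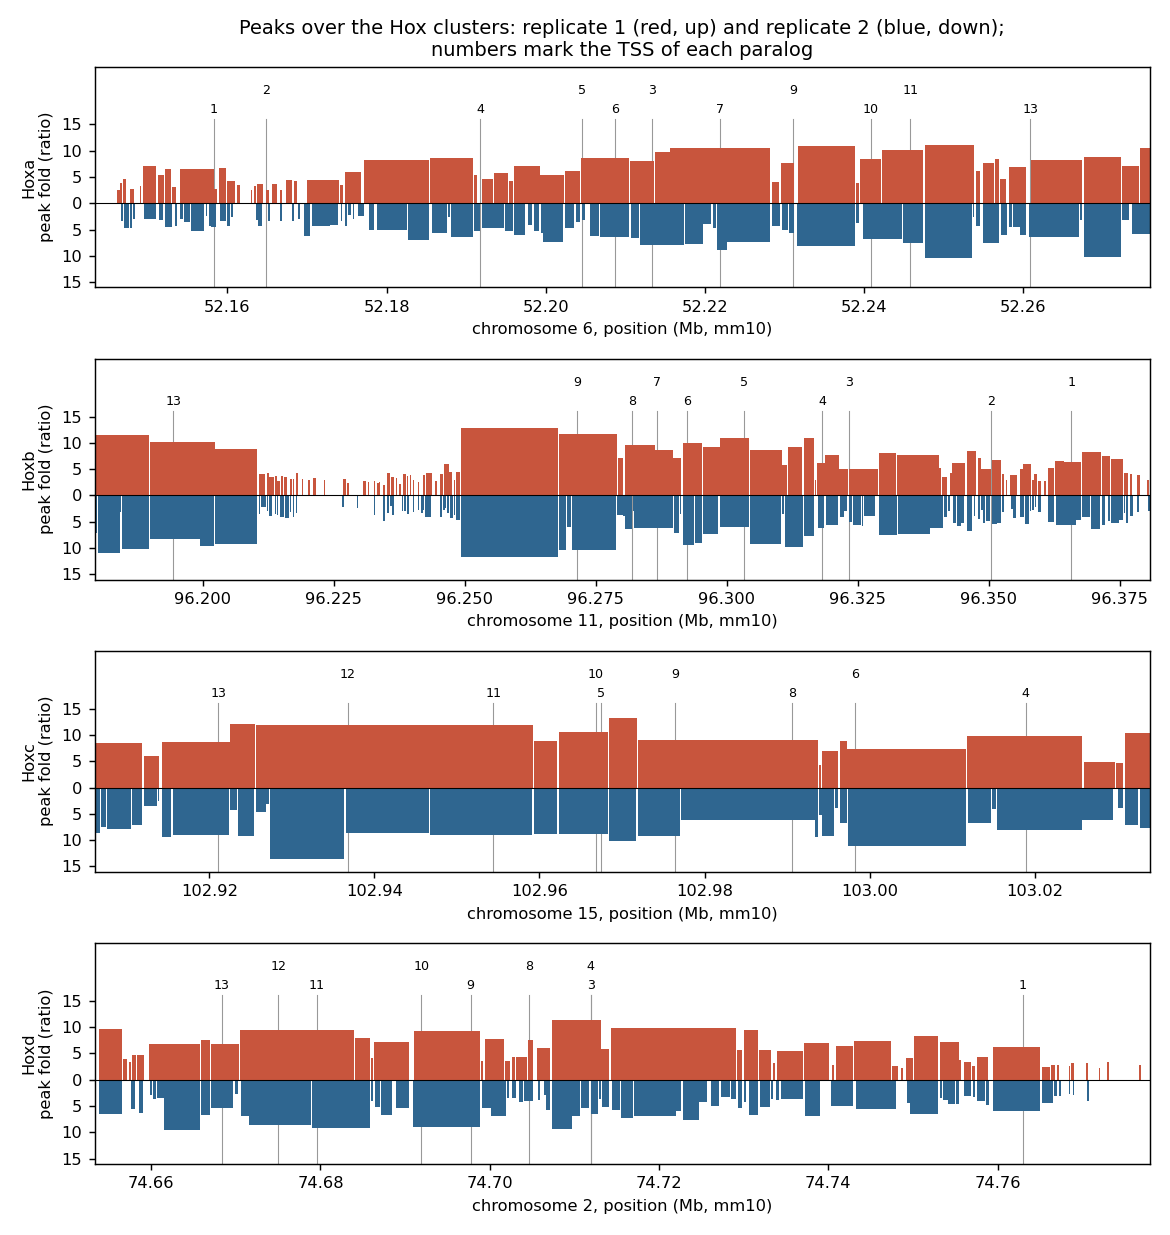
Peaks over the 4 Hox clusters on mm10, with the authors' peak fold upward for replicate 1 and downward for replicate 2, and lines at the annotated TSS of each paralog, by position in Mb. Peaks over Hoxa2 reached 3.69 and 4.28 in replicates 1 and 2, against 11.6 and 10.3 over Hoxb9.

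CpG-rich promoters, the kind at which polycomb complexes are known to assemble, were marked more often than others. Of 8430 CpG-rich promoters 1596 were marked, 18.9%, and of 13508 others 1794, 13.3% (Fisher's exact test, two-sided, p = 6.3e-29, odds ratio 1.52, 95% interval 1.42 to 1.64). The replicates' own lists gave 17.6% ± 2.24 and 12.1% ± 2.49 (SD, n = 2), with the CpG-rich share higher in both. The others, called CpG-poor here, are all promoters that missed either bound in the 1 kb around the annotated 5′ end. The class therefore includes intermediate promoters and does not show that a CpG island is lacking. Of the 16 Hox paralogs 9 to 13, for example, 10 counted as CpG-rich. Of the 1794 CpG-poor marked promoters, 87, or 4.85%, lay in a domain that also held the TSS of a CpG-rich marked gene.

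The X chromosome, of which female cells keep an inactive copy known to carry H3K27me3, was covered more than most autosomes in replicate 1 and less distinctly in replicate 2. Replicated peaks covered 2.58% of X and on average 1.64% ± 0.585 (SD over 19 chromosomes) of the autosomes, a ratio of 1.57. X ranked 3 of 20 behind chromosome 19 with 2.91% and chromosome 11 with 2.73%, and chromosome 3 was lowest with 0.819% (exact rank p = 0.30, two-sided, with 0.1 the smallest possible). The ratio was 1.59 in replicate 1 and 1.17 in replicate 2, where X ranked 7 (exact rank p = 0.70), a mean of 1.38 ± 0.298 (SD, n = 2). Replicate 1's peaks covered 2.13 times as many bases of X as replicate 2's, against 1.48 to 1.66 times on the autosomes. Of the covered bases on X, 4.76% lay in TSS windows, against 12.5% on the autosomes. The share of all bases in TSS windows was not computed for X and autosomes apart, so this gap was not set against gene density. Chromosome Y had no peak.

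**Figure D3:**
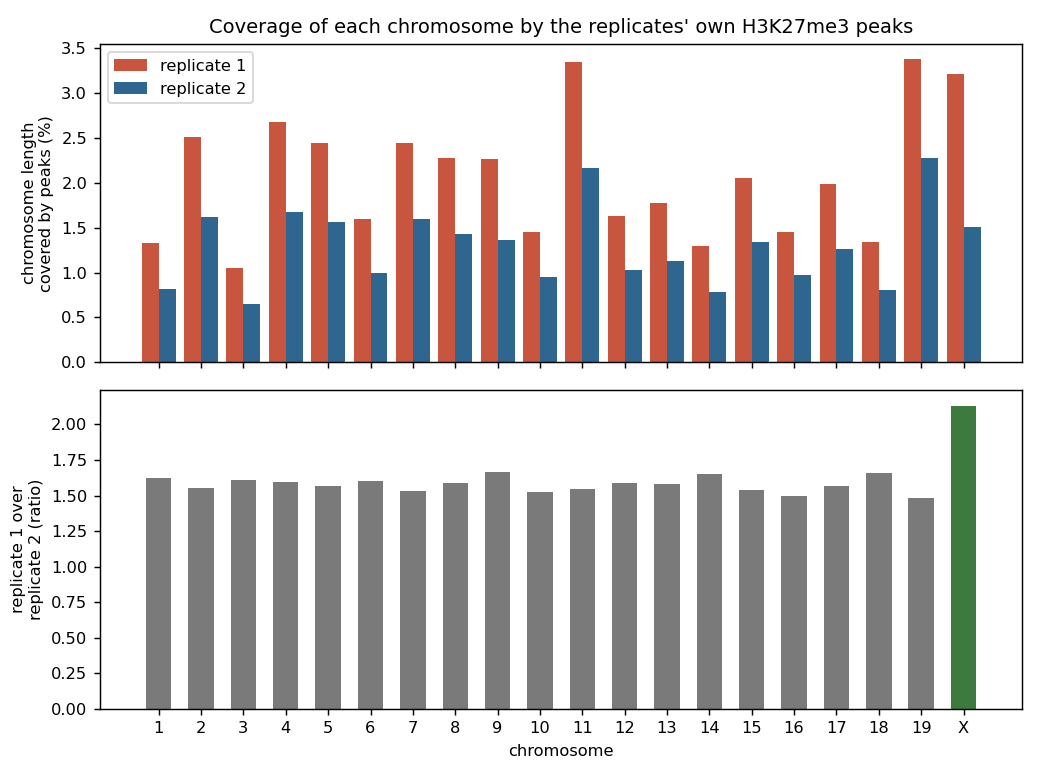
Percent of each chromosome's length covered by the own peaks of replicate 1 and replicate 2 (upper panel, bars) and the ratio of replicate 1 to replicate 2 (lower panel). The ratio was 2.13 on X and between 1.48 and 1.66 on the autosomes.

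Genes on X did not differ by the test from autosomal genes in how often they were marked, 158 of 948 (16.7%) against 3232 of 20807 (15.5%; Fisher's exact test, two-sided, p = 0.36). The difference was 2.87 percentage points with replicate 1's own list (Fisher's exact test, p = 0.021) and -0.730 with replicate 2's (p = 0.55). It also turned to -0.569 with 1000 bp required and to -1.79 with windows of 2.5 kb on each side. Among CpG-rich promoters alone, 60 of 173 on X were marked (34.7%) and 1536 of 8256 on autosomes (18.6%; Fisher's exact test, two-sided, p = 6.7e-07, odds ratio 2.32, 95% interval 1.66 to 3.22). That difference held in replicate 1 with 34.7% against 18.9% (Fisher's exact test, p = 1.2e-06) and in replicate 2 with 28.3% against 15.8% (p = 3.6e-05). Among CpG-poor promoters the shares were 12.6% on X and 13.5% on autosomes (Fisher's exact test, p = 0.52), with X below the autosomes in replicate 2 (8.26% against 10.6%, p = 0.040) and not in replicate 1 (15.2% against 13.9%, p = 0.31).

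Around promoters the mark was enriched, but most covered bases lay elsewhere. TSS windows held 11.7% of the covered bases and 1.60% of the genome, a ratio of 7.30, with 10.8% ± 1.73 (SD, n = 2) in the replicates' own lists and 1.48% to 1.87% in 100 shuffled lists. Exons outside those windows held 8.33% of covered bases against 3.37% of the genome, a ratio of 2.47. Introns held 35.5% against 36.2%, and intergenic DNA 44.5% against 58.9%, ratios of 0.980 and 0.756. The classes were built from protein-coding genes only, so intergenic DNA here includes genes of other types.

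The Hox clusters formed the widest domains once replicated peaks were merged across gaps of up to 1 kb. HoxC, from Hoxc13 to Hoxc4, lay in 172.5 kb on chromosome 15 (102900264 to 103072769, mm10), HoxA from Hoxa2 to Hoxa13 with Evx1 in 165.9 kb on chromosome 6 (52163255 to 52329170), HoxD with Evx2 in 126.9 kb on chromosome 2 (74642197 to 74769053) and HoxB from Hoxb9 to Hoxb2 in 114.7 kb on chromosome 11 (96238201 to 96352903). After them came domains over Dbx1, a progenitor factor of spinal cord and hindbrain interneurons, with 101.1 kb on chromosome 7 (49613695 to 49714822), and Nfix, a factor of neural stem cells and muscle, with 77.8 kb on chromosome 8 (84731712 to 84809492). The domain that ranked 7, of 73.5 kb on chromosome 4 (154443279 to 154516731), held no TSS of a protein-coding gene and lay inside the body of Prdm16, a gene chosen after its values were seen. Domains over Dmbx1 on chromosome 4 (115914923 to 115987233), Tbx3 on chromosome 5 (119648340 to 119717079) and Pax7 on chromosome 4 (139794377 to 139859380) spanned 72.3, 68.7 and 65.0 kb. Replicate 1's own peaks covered 80.8% to 95.4% of each of these 10 and replicate 2's 57.5% to 90.4%, lowest in both at the Prdm16 domain. Of 28870 domains, with a median width of 522 bp, 773 were at least 10 kb wide, and 480 of those (62.1%) held a TSS against 2738 (9.48%) of all. A wider domain holds a TSS more often by its width alone. No share for randomly placed domains of the same widths was computed, so the gap does not show an enrichment of wide domains at TSSs. The choice of 10 depended on the gap: 2 of them were among the widest 10 without merging, and 4 with gaps of up to 3 kb.

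Peaks of the replicates overlapped far more than shuffled ones, most of all the strong peaks. In the strongest 10% of its peaks by the authors' −log10 p, replicate 1 had 91.0% overlapped by a peak of replicate 2, and replicate 2 had 99.4% overlapped by one of replicate 1. In the weakest 10% the shares were 14.0% and 39.9%. Over all peaks 33.4% of replicate 1's (43452 of 129989) and 62.8% of replicate 2's (49736 of 79149) were overlapped by at least 1 bp, against at most 2.58% and 4.34% in 100 shuffles. The lists shared 23.5 Mb of the 64.4 Mb covered by either, a Jaccard index of 36.5% (at most 0.968% in shuffles). Across genes, which are not independent replicates, the percent of the TSS window covered had a Spearman correlation of 0.822 between replicates. Shares of overlapped peaks depend on list length, since the list with fewer peaks meets more of its own in the other.

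**Figure D4:**
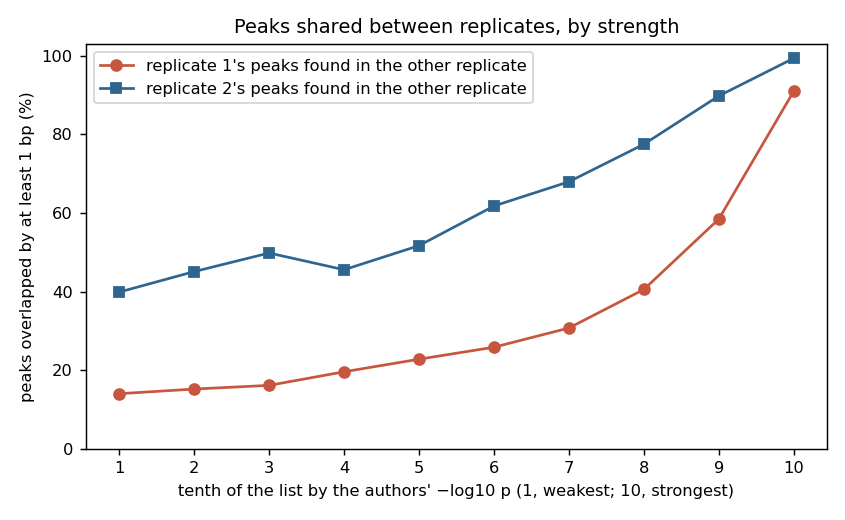
Percent of peaks overlapped by at least 1 bp of the other replicate's peaks, in bins of 10% of each list ordered by the authors' −log10 p, for replicate 1 (circles) and replicate 2 (squares). The share rose from 14.0% to 91.0% in replicate 1 and from 39.9% to 99.4% in replicate 2 between the weakest and the strongest bin.

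The authors' replicated list was a selection from their pooled peaks. All 56974 replicated peaks had the start and end of a pooled peak, of which there were 144083. Of the pooled peaks 36994, or 25.7%, overlapped a peak of each replicate by at least 50% of either peak, and all 36994 were in the replicated list. The other 19980 replicated peaks did not meet that overlap with both replicates: 14311 met it with replicate 1 only, 4207 with replicate 2 only and 1462 with neither. Their median fold was 2.72, between 3.26 for replicated peaks that overlapped both and 2.39 for pooled peaks left out of the list.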

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

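Tests by Hox fold, at principal transcript starts, without chromosome Y and with equal numbers of X peaks were chosen after seeing the data; the other alternatives were planned. The higher share of marked genes among CpG-rich promoters passed the test under every alternative run, with differences of 5.08 to 8.66 percentage points, while the number of marked genes ranged from 2528 to 4570. The Jaccard index of the replicates was 37.7% with q at most 0.05, 45.4% with q at most 0.001 and 41.4% with equal numbers of peaks. The overlapped share of replicate 1's peaks was 31.1%, 34.2% and 44.3% in those settings and 23.1% with 50% of the peak required, and that of replicate 2's was 66.8%, 74.1%, 53.6% and 53.4%. Equal numbers lower replicate 2's share by construction, since replicate 1's list is shortened, and the cause of the other shifts was not tested. Hox coverage differences ran from 4.77 to 13.6 when either replicate was left out, passing only in replicate 2's own list, and by fold the difference was 2.51 at gene starts and 3.22 at principal starts. The X to autosome ratio ran from 1.17 to 1.59 when either replicate was left out. The difference in marked genes between X and autosomes ran from -0.730 to 2.87 points when either was left out, and was 3.17 with the pooled list, 16.1 among CpG-rich promoters, -0.569 with 1000 bp required and -1.79 with 2.5 kb windows. The enrichment of TSS windows was 5.75 with the pooled list and 5.96 to 7.48 when either replicate was left out. Of the 10 widest domains, 2 stayed without merging, 4 with gaps of 3 kb and 6 to 9 when either replicate was left out. With 1 gene per 100 kb, 18 lists lay above the rest and 4 below, with fewer genes tested. Apart from pluripotency genes, the reversed lists passed the test neither in the main setting nor where reversed. Among CpG-rich promoters the differences from the rest were -8.94 points for semaphorins, 1.07 for polycomb genes and 18.6 for cytochrome P450 genes; pluripotency genes, which had passed, moved to -2.27. With 1 gene per 100 kb they were 2.73 for mature glia, 4.95 for protocadherins and -2.28 for cadherins. When either replicate was left out they ran from -0.515 to 2.88 for polycomb genes, -4.18 to 0.768 for microglia markers and 2.87 to 14.9 for mature glia. Mature glia reached 13.2 with the pooled list, 17.6 with 1 bp required, 3.86 with 1000 bp and 7.37 with 2.5 kb windows. Polycomb genes reached 6.10 with 1 bp and 3.52 with 2.5 kb, protocadherins 0.222 and 0.0772, and microglia markers -3.19 with 1000 bp. For these reversals the cause was not tested. No paired analysis was possible because there was 1 group, and the depth, which limits which weak peaks could be called, is unknown.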

Other observations

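The test of a few loci on X by the ratio left without them, the values of the segment where X bins clustered, the comparison of hindbrain with forebrain regulators and that of pan-neural genes with mesoderm and endoderm regulators, were chosen only after the result was seen; the tests of the uneven spread over X were written after the counts of bins were seen and before their own results, and the Hox fold difference was seen before its explanations were written.

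Replicate 1's peaks covered X, relative to autosomes, more than replicate 2's did, with X to autosome ratios of 1.59 and 1.17. The tables argue against the number of peaks alone as the cause, since replicate 1 kept a ratio of 1.52 with as many peaks as replicate 2 (79149). Its shortened list still covered 42.15 Mb against replicate 2's 33.6 Mb, so equal numbers did not match the lists in coverage. An effect of depth, which is unknown, was not tested. GC and repeat content were argued against too, since autosomal bins matched on both had a replicate 1 to 2 ratio of 1.49 (95% bootstrap interval 1.42 to 1.57). On X the ratio was 2.133 (2.003 to 2.295). A few loci met the criterion written beforehand: 80 of 154 X bins, 51.95% (95% exact interval 43.8 to 60.1), lay above the autosomes' ratio, against 57.45% of autosomal bins, and 12 bins (7.79%) held 50% of the excess. That criterion was replaced because the median X bin held only 0.722 kb of replicate 2's coverage; without those 12 bins X kept a ratio of 2.035 (1.865 to 2.277), above the midpoint of 1.85 to the autosomes' 1.57, and 64 of 77 better covered X bins (83.1%) lay above against 59.8% of 1731 autosomal ones, which argues against a few loci but by a test chosen afterwards. A different share of female embryos in the pools stays open and untested, as the labels give no shares, and no biological explanation was tested.

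The excess on X was unevenly spread over its bins, largely as the coverage itself was: the 12 bins that held 50% of the excess also held 44.10% of replicate 2's covered X bases, and X without them kept a ratio of 2.035 against 2.133 for all of X. An excess held by gene-rich bins was argued against, since the ratio was 2.09 in gene-rich X bins and 2.27 in the others, a difference of -0.177 (95% bootstrap interval -0.454 to 0.126). The test was written for that direction only, so it could not decide on an excess held by gene-poor bins. Autosomal bins split at the same number of genes had ratios of 1.550 with more genes and 1.699 in the others. A single segment was argued against as the whole cause, since those 12 bins spanned 159.0 Mb, and 71.00 Mb without the bin farthest from the others. The bins did cluster: 7 of the 12 lay between 160.0 and 170.0 Mb, a segment with 37.27% of all the excess on X and 25.55% of replicate 2's covered X bases, where the ratio was 2.390 against 2.045 (95% bootstrap interval 1.906 to 2.255) on the rest of X. The segment was placed where most of these bins lay, and the bins had been picked for their excess. A larger share of the excess than of the coverage was thus partly set by that choice. How much the choice alone would give was not computed. What else lies behind it stays open, and no biological explanation was tested.

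Averaged over the genes of all clusters, peak folds were lower at Hox paralogs 1 to 4 than at paralogs 9 to 13 in both replicates. Within HoxD the order was reversed in replicate 1 (9.60 against 8.79) and not in replicate 2 (6.34 against 8.22). Promoter base composition was argued against as the whole cause, since 85.1% of the difference in log2 fold remained after it in replicate 1 (permutation p = 0.033) and 89.9% in replicate 2 (permutation p = 8.6e-04). A candidate explanation is a mark carried by part of the cells at regulators the tissue uses, and its criterion written beforehand was met: 41 marked hindbrain regulators had lower log2 folds than 26 of mesoderm and endoderm, by -0.34 in replicate 2 (-0.3350, permutation p = 0.0047) and -0.26 in replicate 1 (permutation p = 0.014). In a comparison that was part of no criterion, the 10 of 30 pan-neural genes that were marked lay below the same 26 genes by -0.84 in replicate 2 and -0.97 in replicate 1 (permutation p = 2.0e-05 each, the smallest the permutations can give). Against 23 forebrain regulators the differences were -0.03 in replicate 2 (permutation p = 0.80) and -0.08 in replicate 1 (permutation p = 0.50), so the condition added afterwards was not met and the hypothesis stays open. Unlike the Hox contrast, none of these contrasts between lists was adjusted for base composition. CpG-rich promoters made up 30 of the 41 hindbrain, 13 of the 23 forebrain, 8 of the 10 pan-neural and 10 of the 26 mesoderm and endoderm genes. Base composition was therefore not separated from these differences.

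Equal numbers of peaks (79149 each) left 587 promoters marked by replicate 1's list alone, 166 by replicate 2's alone and 2579 by both, so that replicate 1 held 77.95% of the promoters marked by a single list (95% exact interval 74.8 to 80.9), against 90.0% with the whole lists. Its shortened list covered 42.15 Mb against replicate 2's 33.6 Mb. The median promoter GC was 56.9% for genes marked by either replicate's whole list alone (interval of the difference -1.40 to 1.30, permutation p = 1.00). These values were computed for a pattern that was then not weighed further.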
